A study of Synechocystis sp. PCC 6803 with 5 samples.

How the data were processed

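Total RNA of 5 cultures, 2 of WT and 3 of ΔpmgA, was hybridised to 1-colour Agilent arrays. Per the labels' protocols, cells were collected on filters of 0.8 µm, and 2 µg of RNA was labelled directly with Cy3. The deposited scanner files hold spot intensity values on a linear scale, made per the file headers with Feature Extraction 10.7.3.1. They give a mean, a median and a local background signal per spot, a background-subtracted processed signal, and flags. A deposited table of the whole series holds log2 values for the same spots. Its values differed by at most 5.00e-09 from log2 raw median signals quantile normalized over all spots, without background subtraction, and each column had a median of 10.99. Its scale is log2 and its direction is that of the signal. The submitters' processing notes name limma.

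Each array had 42303 spots, 40886 of them not controls. Spots with an outlier flag (5 to 9 per array) were left out, and saturated spots were 0. The main setting was log2 of the processed signal minus the array's 75th percentile over non-control spots. The spots of a probe (2 as a rule) were averaged, then the probes of a feature, under the feature names in the scanner files. A feature was tested if at least 1 of its probes was well above background on at least 2 arrays. The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg over the 6201 features tested. The threshold was an adjusted p of 0.05. The fit had 3 residual degrees of freedom and 3.96 prior ones. Where a feature was not well above background on any array of a group, its change is given as at least N-fold: the mean of the bright group over the dim group's mean of, per array, the higher of the feature's own value and the lowest value of a probe well above background.

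Gene lists (22 lists, 320 locus tags) were tested on mRNA features with limma's camera, at a preset correlation of 0.01 and with an estimated one, and with fry. Named features followed a rule set before the data were examined. It took pmgA, Ncr0700 and their neighbours. It took the 12 largest rises and 12 largest falls among mRNAs that passed with all ΔpmgA arrays on one side of both WT arrays, and 5 each way among antisense, non-coding and UTR features. From each list it took up to 4 members that passed, or 2 given as values where none did. Chance alone puts 20% of features with all arrays of one genotype on one side. Functions of genes are background knowledge. The gene table at hand covers another substrain under other tags, and no coordinates were used here.

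The code was tested on simulated data made from the means and spreads of the 6201 features, with 200 of them changed. Of the features changed by 2 on the log2 scale 72.7% were recovered, of those changed by 1 10.4%, and of those changed by 0.5 0%. Of the unchanged features 2 were called. The simulation gave 57 calls and the data 1348, and with more calls the adjusted threshold is less strict. Recovery in the data may therefore differ from these shares. Simulated noise was independent between features, so the test does not cover features that vary together.

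Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, the deposited log2 values, no filter and a stricter one, slide and replicate number as blocks, the median over probes, probes one by one, a trended and a robust prior, and each array left out. Chosen after seeing the data were the 75th percentile over probes detected on all arrays, a mean over detected probes only, and slr1349 in place of slr1350 in 1 list.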

Results

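RNA of the cyanobacterium Synechocystis sp. PCC 6803 was measured on 1-colour Agilent arrays. A glucose-tolerant wild type (WT, n = 2 cultures) was compared with a strain derived from it that lacks pmgA (sll1968), written ΔpmgA (n = 3 cultures). The cultures grew at 30 °C and 50 µmol photons per square metre and second, in medium held at pH 8.0 and bubbled with air enriched to 3% CO2. The RNA itself carried the Cy3 dye, with no cDNA step, so that each probe read 1 strand. The array held 20363 probes for 8830 features: mRNAs, antisense and non-coding RNAs, 5'UTRs, transcripts that start inside genes, stable RNAs and CRISPR-type spacers. Between 38.6% and 58.6% of the spots lay well above background on an array, and no spot was saturated. The number of arrays limits the precision of each value below.

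The first question was whether the arrays bear out the genotype in the labels. The probe of sll1968 with the highest WT signal read 1.76 ± 0.03 (SD, n = 2) in WT, on the log2 scale relative to the array's 75th percentile. In ΔpmgA it read -3.96 ± 0.52 (SD, n = 3) and was not well above background on any of the 3 arrays, which puts the fall at 11.2-fold or more. The other 3 probes of the gene were dim in WT, with means of -2.53, -3.72 and -0.63, and in ΔpmgA they read -3.52, -3.95 and -1.62. The mean over the 4 probes was -1.28 ± 0.12 in WT and -3.26 ± 0.42 in ΔpmgA, a log2 fold change of -1.98 (SE 0.28, limma adjusted p = 0.00402). It lay below both WT arrays in all 3 ΔpmgA arrays. Which of these probes lie inside the deleted part is not given in the sources used here.

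**Figure D1:**
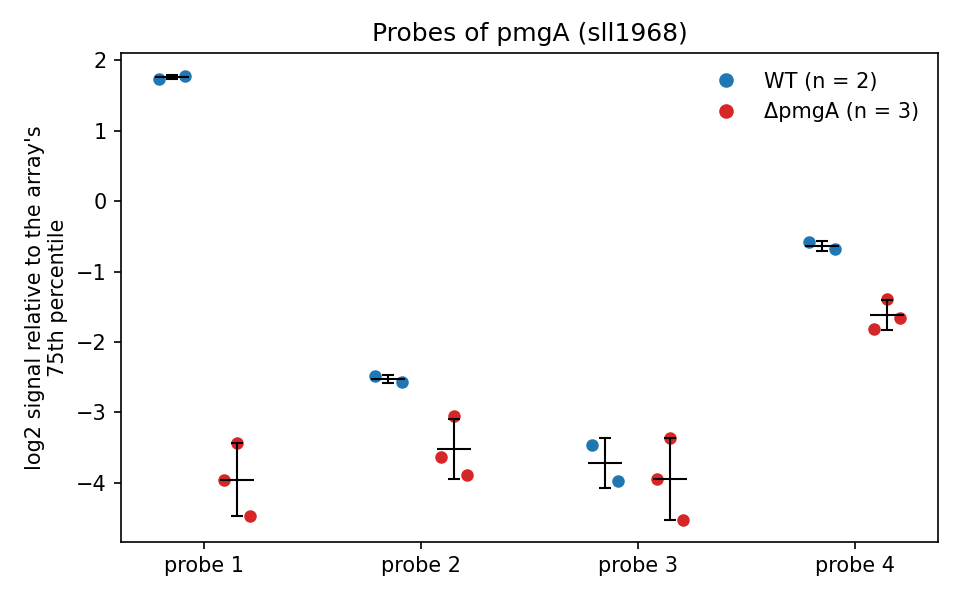
Signal of the 4 probes of pmgA (sll1968) on each array, as log2 of the processed signal relative to that array's 75th percentile. Points are arrays, WT in blue and ΔpmgA in red, with the mean and SD in black. Probe 1 reads 1.76 on average in WT and -3.96 in ΔpmgA.

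Of the features that border pmgA by locus tag, sll1969 had a log2 fold change of -0.38 (SE 0.25, adjusted p = 0.345) and the antisense RNA sll1967-as1 one of 0.05 (SE 0.28, adjusted p = 0.927). Neither passed. Of the 4 probes of sll1969 only 1 was well above background on at least 2 arrays, and on that probe alone, a choice made after seeing the data, the change was -0.88 and passed (adjusted p = 0.0415). The 1 such probe of sll1967-as1, of 2, gave -0.47 (adjusted p = 0.376). sll1967 was too dim to be tested. Ncr0700 (PmgR1), the non-coding RNA of the study's title, was not analysed here, because no feature name on the array could be matched to it.

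The main comparison asked which transcripts differ between ΔpmgA and WT. The 12 mRNAs with the largest fitted rises included slr1251, a cyclophilin-type peptidyl-prolyl isomerase, with a log2 fold change of 3.45 (SE 0.22). Others were slr1350 (desA, a fatty acid desaturase) with 3.01 (SE 0.22) and sll1398 (psb28, a photosystem II assembly factor) with 2.87 (SE 0.21). slr0083 (crhR, an RNA helicase) rose by 2.41 (SE 0.23) and ssl1633 (hliC, a high-light-inducible protein) by 2.55 (SE 0.49). slr1761, slr1600, sll1852, ssl3044, sll1796 and slr0601 were at 2.66, 2.53, 2.48, 2.39, 2.31 and 2.29. The probes of a gene could differ widely, from 0.48 to 3.90 for slr1600 and from 0.99 to 4.04 for slr0601. Those of slr0083 ran from 2.26 to 2.58. In alternatives other than leaving out an array, calls were lost for slr0601 (3 of 14), ssl1633 (2 of 13), ssl3044 (1 of 14) and sll1796 (1 of 14). slr1646, a ribonuclease III, was not well above background in either WT array, and its rise is at least 3.60-fold, which gives it no rank.

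The 12 with the largest fitted falls included slr0474 (rcp1) and slr0473 (cph1), the response regulator and the phytochrome of a light-sensing pair, at -3.45 (SE 0.27) and -3.38 (SE 0.28). Norf1 was at -3.22 (SE 0.26), ssr2227 at -3.13 (SE 0.23) and slr0888 at -3.01 (SE 0.30). sll1196 (pfkA1, a phosphofructokinase of glycolysis) fell by 2.61 (SE 0.28). It was well above background on 1 of 3 ΔpmgA arrays, and that value averages 4 probes of which 1 was so on at least 2 arrays. That probe alone, a choice made after seeing the data, gave -3.62. ssl1046, slr2052, slr0163 and slr1546 were at -2.98, -2.82, -2.48 and -2.48. Single probes ran from -4.25 to -0.13 for slr1546 and from -3.91 to -0.68 for slr0163, against -3.14 to -2.52 for slr2052. Norf8 was at -2.64 (SE 0.69), and at -3.40 without ΔpmgA replicate 2. Its call was lost without any 1 of the other 4 arrays (adjusted p from 0.0563 to 0.142), and with no filter (0.0651) or the deposited values (0.0533). slr0301 (ppsA, phosphoenolpyruvate synthase) was not well above background in any ΔpmgA array, and its fall is at least 1.56-fold, which gives it no rank. Of the 4 probes of slr0301 only 1 was well above background on at least 2 arrays. By the rule that picked them, these 24 genes passed in limma with each ΔpmgA array on the same side of both WT arrays. Each SE measures spread between arrays and not between the probes of a gene.

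**Figure D2:**
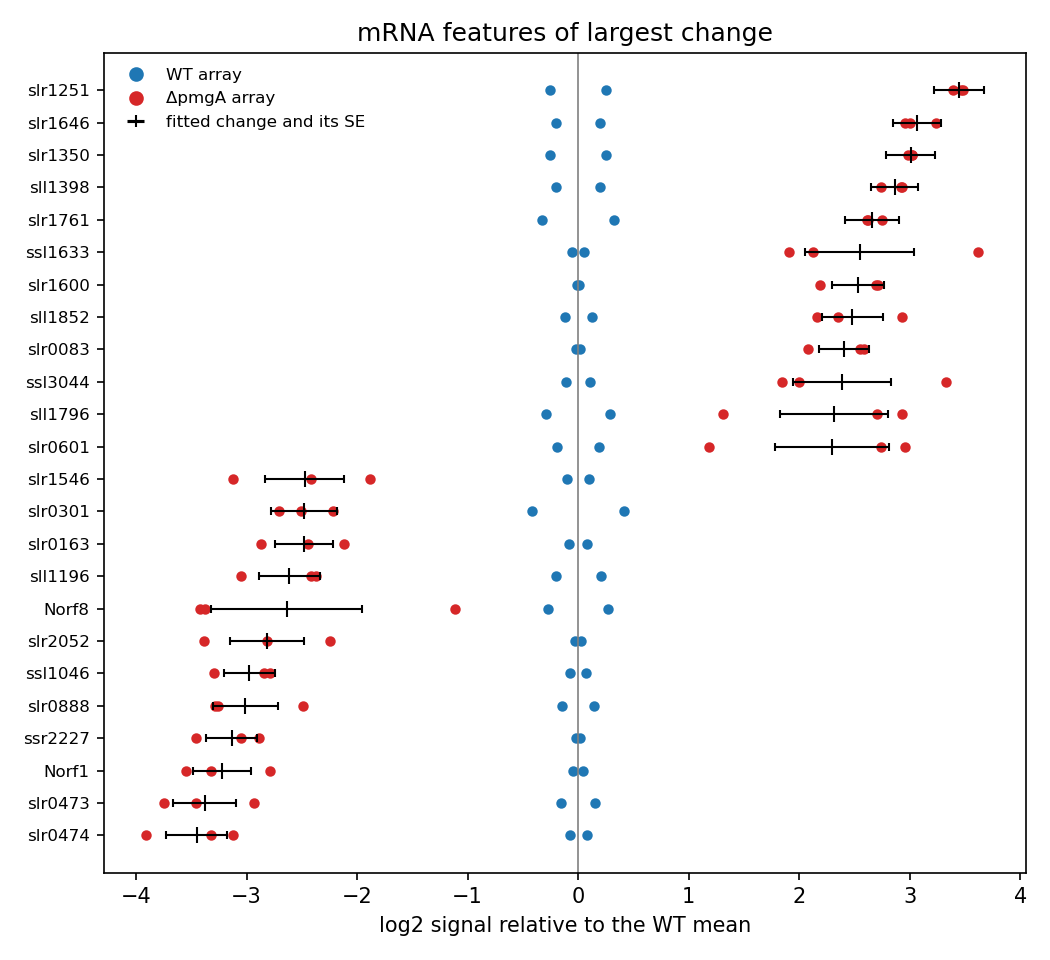
The 12 mRNA features with the largest rise and the 12 with the largest fall, as log2 signal on each array relative to the WT mean. Blue points are WT arrays, red points are ΔpmgA arrays, and the black mark is the fitted change with its SE. The changes run from -3.45 for slr0474 to 3.45 for slr1251, and those of slr1646 and slr0301 are fitted values for genes with only a bound.

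In all, 6201 features were bright enough to test, and 1348 of them (21.7%) passed an adjusted p of 0.05 in limma. Of these, 707 were higher and 641 lower in ΔpmgA, and 500 and 503 changed at least 2-fold. Which direction held more calls depended on the scaling: 575 were higher and 693 lower with median centring, 636 and 721 with normexp and 75th percentile, and 733 and 565 with the 75th percentile of detected probes, chosen after seeing the data. Among 2581 mRNAs, 281 rose and 179 fell. The count rests on the 2 WT cultures: without WT replicate 1 it was 578 and without WT replicate 2 it was 371. The arrays came from 2 slides, each scanned in a session of its own and each holding both genotypes. Slide 1 held WT replicate 1 and ΔpmgA replicates 1 and 2, and slide 2 held WT replicate 2 and ΔpmgA replicate 3. A value within a slide therefore rests on 1 WT array, and within slide 2 also on 1 ΔpmgA array. With slide as a block 1489 features passed, 1291 of them among the 1348. The log2 fold changes of the 2 slides correlated across all tested features with a Pearson r of 0.895. Features are not independent replicates. The slide itself had an effect on 0 features in limma after adjustment and on 947 of 6201 at an unadjusted p under 0.05. That is more than this threshold passes by chance alone, so the 0 does not exclude a slide effect. Across features the WT arrays correlated at 0.988, the ΔpmgA arrays at 0.965 to 0.982, and arrays of different genotype at 0.910 to 0.942.

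Non-coding RNAs changed most often: 164 of 451 tested passed (36.4%), 58 higher and 106 lower. Of the antisense RNAs 193 of 1013 passed (19.1%), of the internal transcripts 331 of 1344 (24.6%) and of the 5'UTRs 138 of 550 (25.1%). Of the mRNAs 17.8% passed. None of the 46 tested tRNAs, rRNAs and other stable RNAs passed in limma, also at an unadjusted p under 0.05, where the count was 0. By Fisher's exact test of each class against all others, two-sided and adjusted over 8 classes, the share differed for non-coding RNAs (1.24e-12), mRNAs (8.70e-10), stable RNAs (4.65e-05), internal transcripts (0.00803), antisense RNAs (0.0326) and other custom features (0.0205). The values for 5'UTRs (0.0584) and for spacers and leaders (0.432) did not pass. Features measured on the same 5 arrays are not independent, so these p-values are descriptive and do not measure spread between cultures. On the array 4011 features had 1 probe and 3053 had 4, and classes were not matched for probe number or brightness. With the mean over detected probes, chosen after seeing the data, Fisher's adjusted p was 0.00143 for mRNAs and 8.84e-10 for non-coding RNAs. How far probe number and the filter account for the shares was not tested. The calls of non-coding RNAs and mRNAs held in each of 19 alternatives, those of stable RNAs in 18, internal transcripts in 14, other custom features in 13 and antisense RNAs in 12. Spacers and leaders passed in 6 of them and 5'UTRs in 3. With slide as a block 5'UTRs passed (0.0122) and other custom features did not (0.0538).

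Among antisense, non-coding and 5'UTR features the 5 picked for the largest fitted rise were NC-2, at 4.51 (SE 0.41), and 4 with only a bound and so no rank. The antisense RNA ssr1736-as1 was not well above background in WT and rose at least 4.25-fold. NC-1115, slr1743-5'UTR and slr0876-as2 were likewise not well above background in WT, with rises of at least 2.75-fold, 2.65-fold and 2.18-fold. The 5 picked for the largest fitted fall included NC-423 at -4.18 (SE 0.27), NC-133 at -3.97 (SE 0.47), NC-1660 at -3.71 (SE 0.30) and NC-717 at -3.15 (SE 0.36). NC-1452 was not well above background in ΔpmgA and fell at least 5.25-fold. The limma adjusted p of these 10 features was at most 0.00255.

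The remaining comparisons concern 22 gene lists fixed before the data were examined. limma's camera, with a preset correlation of 0.01 between genes, called 8 of them. With a correlation estimated from the arrays it called 0, and the smallest unadjusted p was 0.147. A call below therefore holds only for the preset correlation.

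In photosystem I, 6 of 12 members fell, 1 rose and 5 did not pass (8 and 1 adjusted over the list alone), with a list median of -0.82. The reaction centre genes slr1835 (psaB) and slr1834 (psaA) were at -1.65 (SE 0.23) and -1.62 (SE 0.24), slr0737 (psaD) at -1.56 (SE 0.29) and ssr2831 (psaE) at -1.27 (SE 0.25). The camera adjusted p was 2.24e-04, and adjusted p = 0.708 with an estimated correlation. In the phycobilisome, the antenna complex, 7 of 13 fell, 1 rose and 5 did not pass (9 and 1 adjusted over the list alone), with a median of -0.90. The rod linker genes sll1579 (cpcC2) and sll1580 (cpcC1) were at -2.13 (SE 0.27) and -2.02 (SE 0.28) and the core-membrane linker gene slr0335 (apcE) at -1.69 (SE 0.21). The linker gene sll1471 (cpcG2) rose by 1.86 (SE 0.23). In camera the adjusted p was 4.90e-04, and adjusted p = 0.708 with an estimated correlation. Within slide 1 and slide 2 the medians were -0.97 and -0.69 for photosystem I and -0.99 and -0.92 for the phycobilisome.

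Of 29 ribosomal protein genes 14 rose, none fell and 15 did not pass (16 adjusted over the list alone), with a median of 0.72 and within-slide medians of 0.78 and 0.58. sll1799 (rplC) was at 2.07 (SE 0.24), sll1816 (rpsM) at 1.67 (SE 0.19), sll1743 (rplK) at 1.64 (SE 0.19) and sll1800 (rplD) at 1.59 (SE 0.21). With camera this list had an adjusted p of 8.68e-06, and adjusted p = 0.708 with an estimated correlation.

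In the list of glycolysis, the oxidative pentose phosphate pathway and the Entner-Doudoroff pathway 6 of 17 tested members fell and 1 rose (the same adjusted over the list alone). Besides sll1196, slr1793 (transaldolase) was at -1.75 (SE 0.24) and sll0329 (6-phosphogluconate dehydrogenase) at -1.39 (SE 0.21). The member that rose is slr1350, a desaturase that was listed by mistake in place of slr1349, the phosphoglucose isomerase. The list as fixed missed the threshold in camera (adjusted p = 0.0583), and with slr1349, at 0.54 (adjusted p = 0.164), in its place the adjusted p was 0.0255. With an estimated correlation the adjusted p = 0.708 for either version. In glycogen metabolism 1 of 7 passed (1 adjusted over the list alone), slr1176 (glgC, ADP-glucose pyrophosphorylase), at 0.95 (SE 0.21). Its call was lost in 2 of 14 alternatives other than leaving out an array. In polyhydroxybutyrate metabolism 2 of 4 fell (2 adjusted over the list alone), ssl2501 (phaP) at -1.91 (SE 0.43) and slr1994 (phaB) at -1.08 (SE 0.23). That camera adjusted p was 0.0167, and adjusted p = 0.708 with an estimated correlation. Its within-slide medians were -0.74 and -1.37, and the stricter filter (adjusted p = 0.131) and the mean over detected probes (0.0670) ended the call. In the list of pyruvate and the tricarboxylic acid cycle, slr0301 fell and slr1934 (pdhA) rose by 0.76 (SE 0.20), a call lost in 7 of 14 alternatives other than leaving out an array. They were 1 fall and 1 rise among 12 (2 and 2 adjusted over the list alone, camera adjusted p = 0.501).

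In the Calvin-Benson cycle without RuBisCO, 4 of 11 members rose and none fell (4 adjusted over the list alone). They were sll0807 (rpe) at 1.85 (SE 0.22), slr0783 (tpiA) at 1.68 (SE 0.20), slr0194 (rpiA) at 1.16 (SE 0.25) and slr0394 (pgk) at 0.86 (SE 0.24). The call of slr0394 was lost in 10 of 14 alternatives other than leaving out an array. The list passed camera at an adjusted p of 0.0259, and adjusted p = 0.708 with an estimated correlation. The call was lost without WT replicate 1 (adjusted p = 0.0691), without ΔpmgA replicate 2 or 3 (0.0558 each) and with the stricter filter (0.162). Within the slides the medians were 0.54 and 0.35. Among carboxysome, carbonic anhydrase and RuBisCO genes 5 of 12 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.120). The shell genes sll1028 (ccmK2), sll1031 (ccmM) and sll1029 (ccmK1) were at 1.21, 1.18 and 1.03 (SE 0.23, 0.20 and 0.20), and slr0012 (rbcS) at -0.98 (SE 0.22). For slr0012 the call was lost in 2 of 14 alternatives other than leaving out an array. Of 13 tested genes in the list of low-CO2-inducible inorganic carbon uptake 2 rose (2 adjusted over the list alone, camera adjusted p = 0.797). They were slr1513 (sbtB) at 1.40 (SE 0.24) and slr1512 (sbtA, a bicarbonate transporter) at 1.20 (SE 0.23). Single probes ran from 0.46 to 2.69 for slr1513 and from 0.19 to 3.04 for slr1512. The median of that list was -0.04 and its mean 0.16. The list also holds low-CO2-inducible genes that are not uptake genes, so these values are not those of uptake alone.

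In ATP synthase 5 of 9 genes rose and none fell (6 adjusted over the list alone), among them sll1322 (atpI) at 1.37 (SE 0.24), slr1330 at 1.33 (SE 0.20), ssl2615 (atpH) at 1.06 (SE 0.25) and sll1323 at 1.03 (SE 0.19). In camera the list had an adjusted p of 0.0305, and adjusted p = 0.708 with an estimated correlation. Without WT replicate 1 the adjusted p was 0.0760, without ΔpmgA replicate 2 or 3 it was 0.0558, and with the stricter filter it was 0.0639, so that the call was lost each time. The medians within the slides were 0.73 and 0.71. In the NDH-1 complex 4 of 16 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.120). The paralogous subunit genes slr0331 (ndhD1) and slr1291 (ndhD2) differed in direction: slr0331 was at -1.78 (SE 0.24), and slr1291, not well above background in WT, rose at least 1.24-fold. slr0261 (ndhH) rose by 1.49 (SE 0.21) and slr1623 by 1.29 (SE 0.25). Of 11 genes for cytochrome b6f and soluble carriers 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.466). sll1796 (petJ, cytochrome c6) was at 2.31 (SE 0.49) and sll0199 (petE, plastocyanin), an alternative carrier, at -0.97 (SE 0.26), a call lost in 7 of 14 alternatives other than leaving out an array. In photosystem II 6 of 24 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.738). Besides sll1398, slr1645 (psb27) and slr0927 (psbD2) rose by 1.32 (SE 0.21) and 1.28 (SE 0.24), and sml0002 (psbX) was at -1.24 (SE 0.23).

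Of 12 tested pilus and motility genes 4 fell, none rose and 8 did not pass (4 adjusted over the list alone), with a median of -0.56 and within-slide medians of -0.50 and -0.70. slr0161 (pilT1) was at -2.41 (SE 0.20), slr0162 (pilC) at -2.10 (SE 0.23), slr0063 (pilB1) at -1.23 (SE 0.20) and slr1274 (pilM) at -1.05 (SE 0.23). The camera adjusted p was 0.00108, and adjusted p = 0.708 with an estimated correlation. Among sigma factors and central carbon regulators 2 of 13 tested rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.738). The AbrB-like regulator genes sll0822 and sll0359 rose by 2.23 (SE 0.20) and 1.18 (SE 0.23), while the sigma factor genes slr1545 (sigG) and slr1564 (sigF) were at -2.15 (SE 0.20) and -1.51 (SE 0.21).

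In the list of heat shock, chaperone and protease genes, kept as a sign of stress and handling, 6 of 17 tested rose and none fell (7 adjusted over the list alone). The list also holds high-light-inducible genes, among them ssl1633. Besides ssl1633, the chaperonin genes slr2075 (groES) and sll0416 (groEL2) rose by 1.38 (SE 0.25) and 1.15 (SE 0.24) and the protease gene slr1604 by 1.08 (SE 0.23). The camera adjusted p was 0.0261, and adjusted p = 0.708 with an estimated correlation. The medians were 1.04 within slide 1 and 0.54 within slide 2. Without WT replicate 1 or without ΔpmgA replicate 1 the call was lost (adjusted p = 0.0981 and 0.0988), as it was with quantile normalization (0.0569), normexp and quantile (0.0646), the deposited values (0.0883) and the stricter filter (0.131).

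Of 18 genes of nitrogen assimilation 4 rose (4 adjusted over the list alone, camera adjusted p = 0.120): sll1451 (nrtB) and sll1450 (nrtA) of nitrate uptake by 1.50 (SE 0.23) and 1.30 (SE 0.25), slr1756 (glnA, glutamine synthetase) by 0.98 (SE 0.25) and sll1515 (gifB, its inhibitor) by 0.73 (SE 0.19). Of 14 alternatives other than leaving out an array, the call of sll1515 was lost in 4 and that of slr1756 in 2. In chlorophyll and tetrapyrrole synthesis 3 of 14 tested rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.341). slr0056 (chlG), slr0525 (chlM) and sll1185 (hemF) rose by 1.66, 1.17 and 1.10 (SE 0.20, 0.27 and 0.23) and sll1184 (ho1, heme oxygenase) was at -1.04 (SE 0.22). The value of slr0525 averages 4 probes of which 1 was well above background on at least 2 arrays, and that probe alone, chosen after seeing the data, gave 1.88. The call of slr0525 was lost with no filter (adjusted p = 0.0522) and with normexp and 75th percentile (0.0553). Of 3 tested genes of the bidirectional hydrogenase 1 fell (1 adjusted over the list alone, camera adjusted p = 0.120), sll1220 (hoxE), at -1.40 (SE 0.23), and at -1.07 with its call lost (adjusted p = 0.163) over detected probes only, chosen after seeing the data. No gene passed in phosphate acquisition, with 9 tested, or in iron acquisition, with 9 tested, also adjusted over the list alone (camera adjusted p = 0.962 and 0.832). Values there were 0.42 for sll0680 (adjusted p = 0.175) and -0.42 for slr1248 (adjusted p = 0.308), and 0.74 for slr1392 (SE 0.73, adjusted p = 0.547), which was 0.01 without ΔpmgA replicate 1 and 0.07 without WT replicate 2. sll0247 (isiA, adjusted p = 0.482) was not well above background in WT and was so in 2 of 3 ΔpmgA arrays, at least 2.48-fold higher on average. The iron-stress gene sll0247 read 3.65 in ΔpmgA replicate 1 and -2.56 and -1.80 in the other ΔpmgA arrays. Its bound rests on replicate 1, and without that array its log2 fold change was 0.09. Both sll0247 and slr1392 passed with replicate number as a block, a fit with 1 residual degree of freedom.

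**Figure D3:**
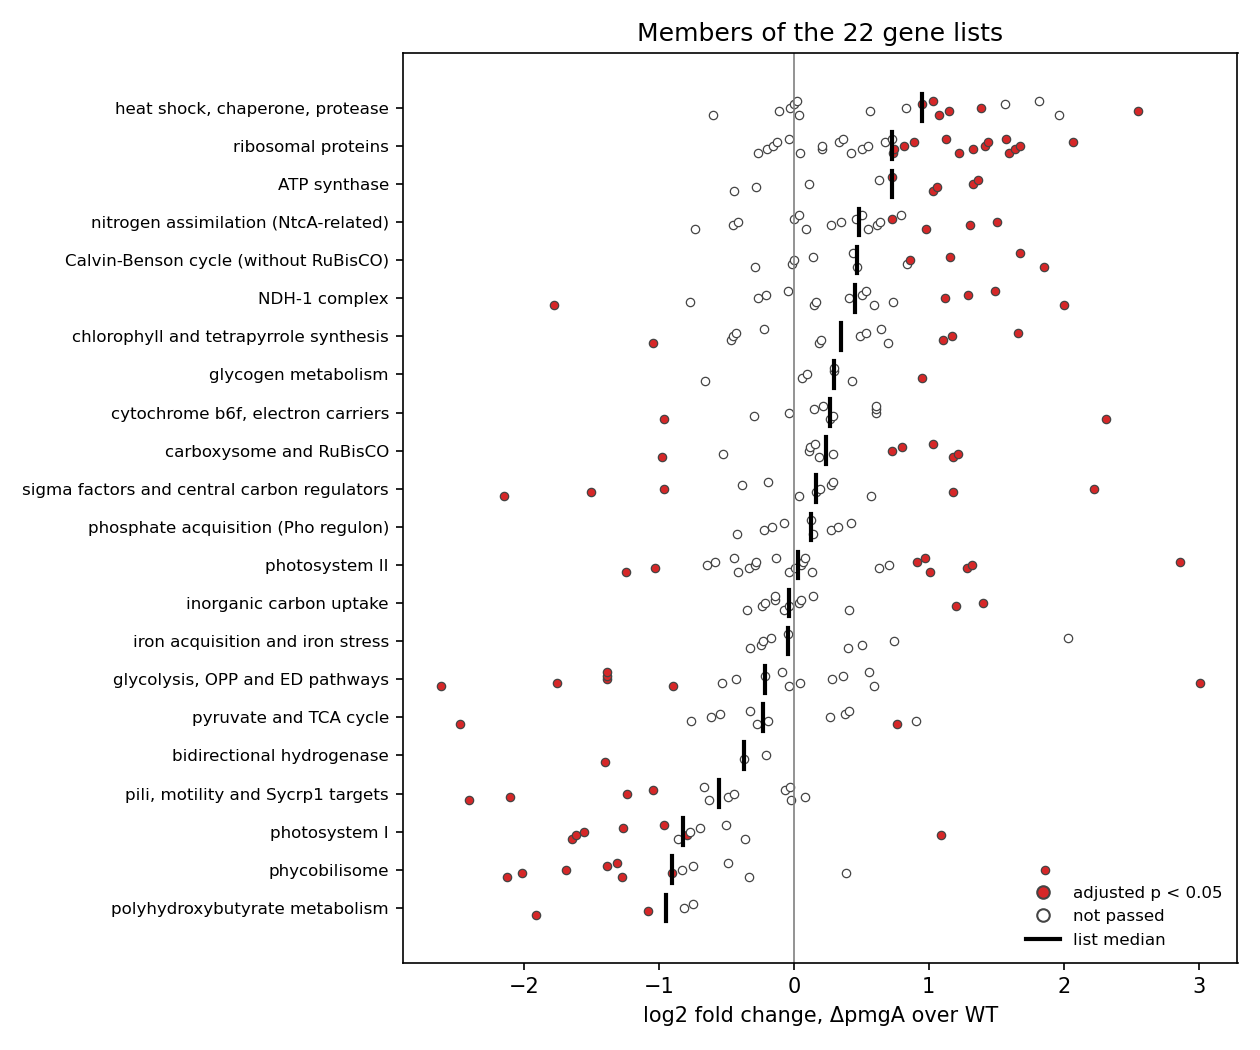
Log2 fold change of ΔpmgA over WT for each tested member of the 22 gene lists, ordered by list median. Red points passed an adjusted p of 0.05, white points did not, and the black bar is the list median, from -0.95 for polyhydroxybutyrate metabolism to 0.95 for heat shock, chaperone and protease genes.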

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

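The scaling on detected probes, the mean over detected probes and the corrected glycolysis list were chosen after the results were seen. The log2 fold change of pmgA kept its direction and its call in each setting that tested it, between -0.56 (deposited values) and -3.35 (detected probes only), and between -2.21 and -1.80 with single arrays left out. The stricter filter did not test pmgA, which was well above background on 1 of 3 ΔpmgA arrays, and tested 66 of the 100 named features. No named feature that passed changed direction. Over 100 named features and the settings other than leaving out an array, 1309 of 1366 values kept their side of the threshold, 54 lost their call and 3 gained one. With single arrays left out, 405 of 500 kept it and 95 lost it, 31 without WT replicate 1 and 46 without WT replicate 2, where the lone WT array is assumed to vary like the others.

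The count of changed features was 2422 when probes were tested one by one, out of 10400 probes, and ran from 371 to 1413 with arrays left out. For mRNAs that range was 112 to 485. Features at least 2-fold higher numbered 205 with normexp and quantile, 184 with normexp and 75th percentile, 96 with the deposited values and 298 with the stricter filter, which tests fewer features, and 177 to 499 with arrays left out. Those at least 2-fold lower numbered 262, 312 and 144 with normexp and quantile, normexp and 75th percentile and the deposited values, and 194 to 515 with arrays left out. Median centring put the median of all features at -0.12. Of the 24 genes of largest change 12 stayed among the features the stricter filter tests. The number of gene lists called was 13 with no filter, 4 with the stricter filter, 0 with an estimated correlation and 0 by fry's test for 1 direction (19 of 22 by its test for either direction), and 5 to 8 with arrays left out. The lists of ribosomal proteins, photosystem I, phycobilisome and pili were called at the preset correlation in each refit, and the Calvin-Benson and ATP synthase lists were lost without WT replicate 1, ΔpmgA replicate 2 or ΔpmgA replicate 3, with the stricter filter and with the replicate block. The glycolysis list as fixed passed with both normexp settings, the deposited values, no filter, the replicate block, both settings on detected probes and without ΔpmgA replicate 3. The number of feature classes called ran from 4 to 7, against 6. The neighbour sll1969 passed with detected probes only (a count of 1 in place of 0). Except for the effects of fewer samples or features, the cause was not tested.

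With the replicate block, using the numbers 1 and 2 that both genotypes share, 1301 features passed. ΔpmgA replicate 3, whose number WT lacks, had no weight in that fit. The log2 fold change of pmgA was -1.80 there, as it was without that array. The replicate block thus leaves out an array in effect, though it is counted above among the settings other than leaving out an array. Same-numbered arrays deviated from their group means with correlations of 0.26 for the pair on 1 slide and -0.28 for the pair on different slides. Number and slide are thus mixed, and these values cannot tell whether the numbers pair the cultures. Arrays of 1 slide gave 0.26, 0.28 and 0.59. With 2 WT arrays, each value has its mirror image in the pair with the other WT array. Background limits all arrays: negative controls reached 76.6% to 85.1% of the median raw signal of the probes.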

Other observations

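The sigma factor gene sll1689 (sigE), named here after its values were seen, was at -0.97 (SE 0.23, limma adjusted p = 0.0251), lower in 3 of 3 arrays. Whether antisense RNAs move against their genes was tested, and no such relation was found: over 791 pairs Spearman's rho across pairs was 0.0083 (permutation p = 0.814), and of 40 pairs with both members past the threshold 16 went opposite ways.

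In the patterns below, the tests of brightness, slide and single arrays for the gene clusters, those of the spacers and that of quantile normalization were chosen after the result was seen. In 4 clusters of the lists, picked because they show it, the log2 fold change lay lower at the following locus tag in 24 of 36 neighbouring pairs (median difference -0.16), as in ATP synthase from 1.37 at sll1322 to -0.44 at sll1327. In the ribosomal cluster it went from 2.07 at sll1799 to -0.27 at sll1811, and was 1.67 again at sll1816. Over 1107 neighbouring pairs of tags outside the lists, the median downstream minus upstream difference was 0.00 (0.000614, sign-flip permutation p = 0.976). Tags outside the lists thus showed no general fall. Which pairs share a transcript is not known here, so a fall along shared transcripts stays open. Within the clusters the median was negative on each slide (the smaller fall -0.17) and in each ΔpmgA array (the smallest fall -0.14). The fall was thus not confined to 1 slide or 1 ΔpmgA array. The clusters were picked for the fall over all arrays, and the ΔpmgA arrays share the WT mean, so these values cannot decide its cause. A gene's coding part lay below its 5'UTR by a median of -0.081 (492 pairs, sign-flip permutation p = 0.00718). That p measures spread across genes and not across cultures, and this small fall remains open. Brightness remains open too. The slope per gene with the WT level included was -0.032, but the slope already reached 0 without it (95% interval -0.07 to 0.01).

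Of 23 tested spacers in the series whose names carry index 1, 20 fell, with a median of -1.90 (-1.73 over the 23), against 1 of 42 and 1 of 19 in the series with index 0 and 2, whose tested spacers had medians of -0.05 and -0.89. Of the 20, 13 stayed well above background on all 3 ΔpmgA arrays, which argues against loss of those 13 from the DNA and leaves it open for the others. Whether the fold falls with spacer number in this series stays open (rho -0.20, bootstrap 95% interval -0.66 to 0.27, permutation p = 0.365, and rho -0.33 over the 15 tested spacers well above background on all 3 ΔpmgA arrays), and that interval holds the rho of the series with index 0 and 2 (-0.52 and -0.62, adjusted permutation p = 0.00138 and 0.00820). The leader feature lay 1.90 above the spacer median, but whether its probe lies inside the transcript is not known here, so that a lower rate of starting transcripts cannot be told apart from other changes. The genotype itself stays among the open explanations.

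The deposited values gave smaller folds than the re-normalized ones, with a slope of 0.43 over the 1348 changed features. The slope rose from 0.22 among the dimmest 337 of them to 0.83 among the brightest 337, a difference of 0.61, which is consistent with a signal common to all probes that was left in. Quantile normalization alone gave a slope of 0.97, which argues against it as the cause. Slopes were also under 1 with normexp and quantile (0.64) and with normexp and 75th percentile (0.66). The size of a fold therefore depends on the processing. No biological explanation was tested for this pattern.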
